A study of Mus musculus with 10 samples.

How the data were processed

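The samples were Th17 cells made from C57BL/6 mouse spleen. Per the labels' protocols, naive CD4 T cells were stimulated through CD3 and CD28 in the presence of IL-6 at 20 ng/mL and TGF-beta at 2.5 ng/mL, and the cultures ran for 48 to 72 h. Cells were exposed to TMP269 before harvest, or to DMSO, the solvent in which such compounds are usually dissolved. The dose of TMP269 and the length of exposure are not given in the sources used here. RNA libraries were made after selection of polyadenylated RNA. The labels put 2 libraries in each of the 2 groups. The control columns of the table are named WT, and they were matched to the DMSO samples by the labels, which give these column names in the descriptions of those samples. The series also holds 6 chromatin immunoprecipitation libraries, 4 for HDAC4 or HDAC7 and 2 inputs, which are not analysed here.

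The deposited table held 1 value per gene and library for 17493 genes. Its values were a normalised signal, each library's read counts divided by a single size factor, as the deposited values themselves showed. Multiplying each library by its own factor returned whole reads for 100% of the values, with a largest deviation of 4.66e-10 from a whole number. The size factors were 1.11 and 0.829 for DMSO replicates 1 and 2, and 0.967 and 1.05 for TMP269 replicates 1 and 2. Per the submitters' processing notes, the tools were CASAVA 1.4, Bowtie2, TopHat2 2.1.0, HTSeq and DESeq2, and the build was mm9. These notes give no role for each tool, and some may belong to the chromatin libraries only. The gene annotation, the strand setting and the handling of reads that match several places are not given in the sources used here. Counts of overlapping genes, antisense partners and genes with near-identical copies or pseudogenes are therefore uncertain. The gene table supplied as a reference used another assembly, GRCm38, so no coordinates are printed. Genes are named by the symbols in the table.

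The planned test assumed raw counts and was a quasi-likelihood test in edgeR with TMM factors. Because the table held normalised values, the test used here was limma (version 3.58.1, in R 4.3.3) on log2(value + 1), with a mean-variance trend in the empirical Bayes step. This change of test was made once the table was seen. Whole reads were recovered, so the planned test could have been run on them. Genes entered the test with a value of at least 10 in at least 2 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and all tests were two-sided. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. The model had no covariate. The prior degrees of freedom were 6.84. The edgeR test (version 4.0.16) with TMM factors was run on the recovered reads, with the filter used for limma in place of the planned one. Its use as an alternative was decided after the data were seen. It called 3406 genes, 1656 higher and 1750 lower. An exact test of 2 against 2 values cannot give a two-sided p below 0.333, so every p-value here rests on the spread that limma shares across genes. The labels do not say whether replicates came from separate animals or cultures. The p-values measure only the spread between these samples, which may be technical.

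A total of 23 gene lists and the rule for named genes were set before the data were examined. The rule named 17 genes of interest whether called or not, and the 6 largest rises and 6 largest falls among called genes with separate groups and a mean of at least 5 CPM in the higher group, leaving out unnamed gene models. It also named up to 2 called members that rose and 2 that fell in each list, taken by the smallest p. This gave 80 genes, of which 74 were called. Some of these are not reported here. Lists were tested against the other tested genes with camera from limma, at a preset correlation between genes of 0.01 and with adjustment over the 23 lists. An estimated correlation and fry were alternatives. Fry asks whether the members of a list move, on balance, one way, without comparing them with other genes. A further 6 lists were chosen after the data were seen and are used only in the closing observations.

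Alternatives were other size factors, total library size, DESeq2 (version 1.42.0), limma-voom, other filters, other thresholds, the replicate number as a block, each library left out in turn and library sizes without the 20 most abundant genes. Other pseudocounts, TMM factors and equal library totals with or without the ribosomal RNA gene Rn45s were added after the data were seen. With 1 library left out, the lone library of a group is assumed to vary like the others.

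The test was tested on simulated data with the means, depths and common dispersion (0.00675) of these libraries, in which 200 of 12510 genes had been changed. For TMP269 against DMSO it recovered 67.6% of 68 genes changed by 1.5-fold, 83.3% of 66 genes changed by 2-fold and 100% of 66 genes changed by 4-fold. Of its calls, 4.57% were genes that had not been changed. Camera passed a simulated list of raised genes and did not pass an unchanged one. Genes were simulated independently, with the same dispersion for all genes and no condition shared by libraries of the same replicate number. The simulation therefore does not cover lists whose members vary together, or genes that vary more than others. Far fewer genes were changed than the 27.5% called in the real data, so these shares may not carry over.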

Results

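Gene expression was measured by RNA sequencing in mouse Th17 cells, the IL-17-producing class of helper T cells, kept with TMP269 or with DMSO. TMP269 is a small molecule that selectively inhibits the class IIa histone deacetylases HDAC4, HDAC5, HDAC7 and HDAC9. There were 2 libraries per group. The recovered reads came to 25321455 and 20007042 in DMSO replicates 1 and 2 and to 20837231 and 23259102 in TMP269 replicates 1 and 2. Reads of the ribosomal RNA gene Rn45s made up 0.836% and 2.20% of the DMSO libraries and 0.716% and 1.12% of the TMP269 libraries, so DMSO replicate 2 stood apart. Across genes, which are not independent replicates, log2 values correlated at r = 0.992 within the DMSO pair, 0.994 within the TMP269 pair and 0.977 to 0.983 between groups. The chi-square per degree of freedom was 22.8 within the DMSO pair and 12.02 within the TMP269 pair. Both were well above sampling noise, so no library was a mere resequencing of another. The chi-square includes Rn45s, whose share differed more within the DMSO pair. It cannot tell separate cultures from separate preparations of the same RNA.

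The comparison of TMP269 with DMSO asks which genes of Th17 cells respond to inhibition of class IIa histone deacetylases, the enzymes named in the study's title. In cells with TMP269 the Th17 cytokine genes Il17a and Il17f fell, all 23 genes of the glycolysis and hypoxia list fell, and 14 of 16 tested p53 targets rose. Among called genes with a mean of at least 5 CPM in the higher group, the 6 largest rises included Cyp1a1, a xenobiotic-metabolising cytochrome P450, which went from 284 ± 45.9 to 3013 ± 662 normalised reads (SD, n = 2), a 10.5-fold rise (limma adjusted p = 3.93e-05). Robo3, a guidance receptor, rose 9.34-fold, the transcription factor gene Zfp750 8.03-fold, the adenylate kinase gene Ak1 6.12-fold, the extracellular sulfatase gene Sulf2 5.78-fold and the mitochondrial creatine kinase gene Ckmt1 5.67-fold. The 6 largest falls among these included the cadherin gene Cdh17, which went from 321 ± 60.03 to 44.7 ± 20.2 normalised reads, 7.36-fold lower (limma adjusted p = 4.85e-04). Selenbp1, a selenium-binding protein gene, was 5.63-fold lower, Kmo, an enzyme of tryptophan breakdown, 5.54-fold lower, and the integrin gene Itga7 4.77-fold lower. Bank1, a B cell adaptor gene, was 3.99-fold lower and the receptor tyrosine kinase gene Flt3 3.97-fold lower.

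Of 12535 genes tested with limma, 3448 (27.5%) were called at an adjusted p under 0.05, 1602 higher and 1846 lower with TMP269. A change of at least 2-fold was seen in 303 of the higher and 169 of the lower genes. In all 3448 called genes, both TMP269 libraries lay on the same side of both DMSO libraries. That held for 66.6% of all tested genes, where chance gives 33.3% on average over assignments of the labels. Genes share the same 4 libraries and are not independent, so the excess does not by itself show an effect of the compound. The count of calls fell to 2078 without DMSO replicate 2 (1063 higher and 1015 lower) and to 2287 without TMP269 replicate 1 (1148 higher and 1139 lower). The split moved with the scaling. Higher genes made up 46.5% of calls with the authors' size factors, 67.3% with equal library totals, 65.7% with equal totals without Rn45s, 67.1% with total library size in edgeR and 62.3% with library sizes without the 20 most abundant genes. Equal totals moved the median log2 fold change of all tested genes from 0.00 to 0.10, so gene changes are given relative to a median near 0.

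**Figure D1:**
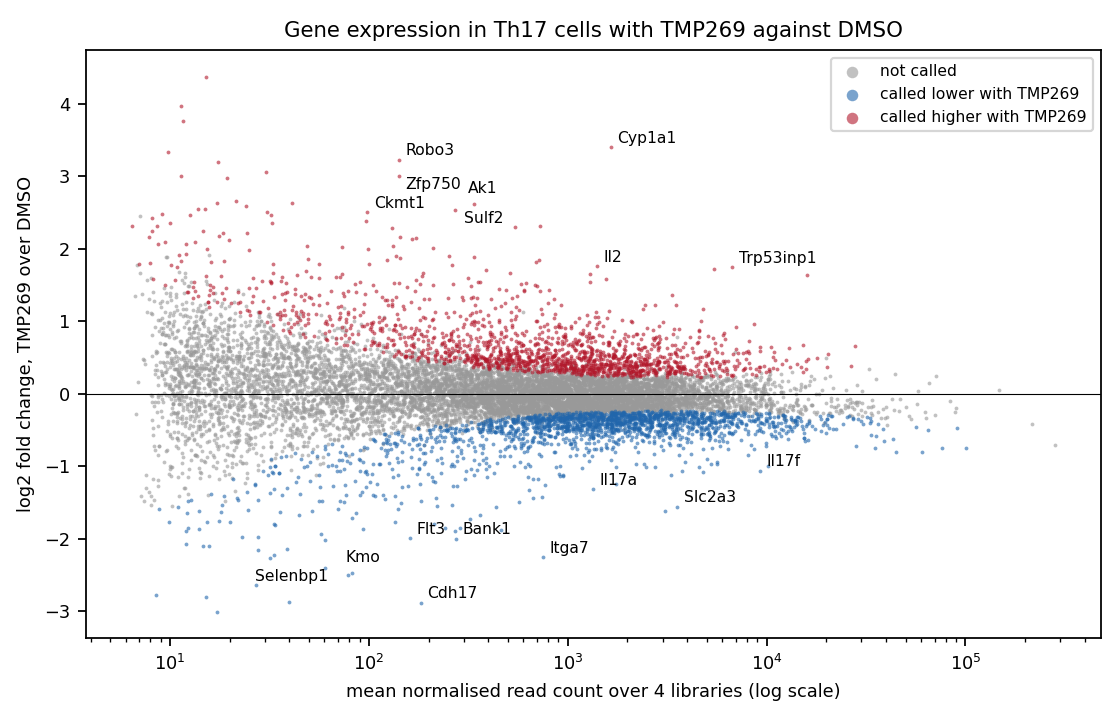
Each point is 1 of the 12535 tested genes, with its mean normalised read count over the 4 libraries on a log x axis and its log2 fold change, TMP269 over DMSO, on the y axis. Colours mark the 1602 genes called higher and the 1846 called lower, and Cyp1a1 and Cdh17 lie near the top and bottom of the well-expressed genes.

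Among Th17 genes, Il17a, Il17f and the chemokine receptor gene Ccr6 fell, while Maf and Il21 rose. Il17a went from 1918 ± 43.4 to 768 ± 25.5 normalised reads (SD, n = 2), a log2 fold change of -1.32 ± 0.08 (SE, limma adjusted p = 1.27e-04). Il17f went from 12455 ± 1004 to 6022 ± 1221 (log2 fold change -1.06 ± 0.13, limma adjusted p = 0.00113), and Ccr6 from 982 ± 41.8 to 435 ± 27.4 (log2 fold change -1.17 ± 0.10, limma adjusted p = 2.21e-04). The transcription factor gene Maf rose 1.48-fold, and the cytokine gene Il21 rose 1.36-fold from 13367 ± 721 normalised reads (limma adjusted p = 0.00836, but 0.0608 without TMP269 replicate 1). Rora, a nuclear receptor gene, was not called (log2 fold change 0.15 ± 0.10, limma adjusted p = 0.298). Il23r, the IL-23 receptor gene, was at 171 ± 35.9 and 119 ± 17.4 normalised reads (log2 fold change -0.52 ± 0.20, limma adjusted p = 0.0872), and passed without DMSO replicate 1 (0.0306) or TMP269 replicate 2 (0.0475). Of the 24 tested members of the Th17 signature, 5 rose, 6 fell and 13 did not pass (6 and 6 adjusted over the list alone). The list did not shift against other genes (median log2 fold change -0.10, camera adjusted p = 0.694), while fry, which makes no such comparison, gave an adjusted p of 0.0244 downward. Its median was 0.00 with equal totals, -0.06 without DMSO replicate 1, -0.02 without DMSO replicate 2 and -0.04 without TMP269 replicate 2, and 3 members rose without DMSO replicate 2 or without TMP269 replicate 1.

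**Figure D2:**
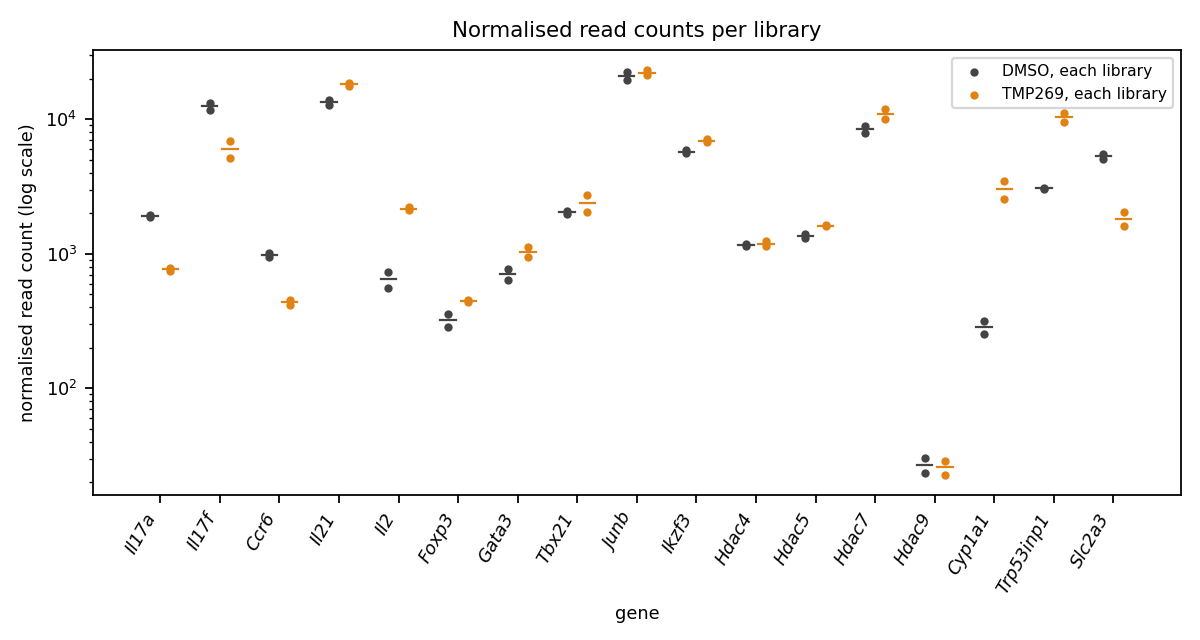
Normalised read counts on a log y axis for 17 genes on the x axis, with 1 point per library (2 DMSO and 2 TMP269) and a line at each group mean. Both TMP269 libraries lie below both DMSO libraries for Il17a, Il17f, Ccr6 and Slc2a3, and above them for Il21, Il2, Cyp1a1 and Trp53inp1.

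Genes of other helper T cell classes moved in both directions. Foxp3, the lineage factor of regulatory T cells, rose 1.399-fold, from 320 ± 48.5 to 446 ± 6.26 normalised reads (SD, n = 2, limma adjusted p = 0.0272), and Gata3, the Th2 factor, rose 1.47-fold (limma adjusted p = 0.0121). The Foxp3 call was lost without DMSO replicate 2 (0.149) or TMP269 replicate 2 (0.0577), and the Gata3 call without DMSO replicate 2 (0.0502). Tbx21, the Th1 factor, was at 2032 ± 57.8 and 2384 ± 488 and was not called (limma adjusted p = 0.229, but 0.0121 without TMP269 replicate 2). Of 20 Treg genes, 5 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.227). Itgae, the integrin CD103, rose 2.81-fold and the Helios gene Ikzf2 1.54-fold, whereas the costimulatory receptor gene Icos fell to 0.503-fold and the inhibitory receptor gene Ctla4 to 0.742-fold (limma adjusted p = 0.00717, but 0.0588 without TMP269 replicate 1). Of 13 Th2 genes, 6 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.198). The chemokine receptor gene Ccr8 rose 1.56-fold, while the transcription factor gene Nfil3 fell to 0.509-fold and Ccr4 to 0.728-fold. Of 19 Th1 genes, 5 rose and 3 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.407). The chemokine genes Ccl3 and Ccl4 rose 2.101-fold and 2.07-fold, and Il18rap, a subunit of the IL-18 receptor, and the homeobox gene Hlx fell to 0.354-fold and 0.365-fold. Of 13 Tfh genes, 3 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.762 downward, median log2 fold change 0.04, mean -0.23). The Tfh median was -0.13 without DMSO replicate 1 and 0.21 without DMSO replicate 2. Tox, a transcription factor gene, rose 1.58-fold, and Pou2af1, a coactivator gene known from B cells, fell to 0.656-fold, as the B cell markers did (list median log2 fold change -0.91). Without DMSO replicate 2, 3 Th1, 3 Th2 and 3 Treg genes rose and 3 Tfh genes fell. Without TMP269 replicate 1, 1 Tfh gene rose and 1 Treg gene fell, and without TMP269 replicate 2, 3 Th2 genes rose.

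Il2, the T cell growth factor gene, rose 3.39-fold, from 645 ± 121 to 2170 ± 93.6 normalised reads (SD, n = 2, log2 fold change 1.76 ± 0.12, limma adjusted p = 1.27e-04). In the IL-2 and STAT5 list, 5 of 16 members rose and 3 fell (7 and 3 adjusted over the list alone), and the list did not shift against other genes (camera adjusted p = 0.208, fry adjusted p = 0.0244 upward). Stat5a rose 1.56-fold, whereas Socs3, a feedback inhibitor of cytokine signalling, fell to 0.728-fold and the growth regulator gene Myc to 0.805-fold. Both falls were lost without TMP269 replicate 1 (limma adjusted p = 0.0526 for Socs3 and 0.0877 for Myc), and that of Myc also without TMP269 replicate 2 (0.124), with total library size in edgeR (0.0833), with equal totals (0.0786) and with equal totals without Rn45s (0.0623). Counts of risen and fallen members in this list were 3 and 2 without DMSO replicate 2, 2 and 0 without TMP269 replicate 1, and 3 and 2 without TMP269 replicate 2.

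Immediate early transcription factor genes, which follow T cell receptor signals, rose as a group. Of 18 tested members of the AP-1 and immediate early list, 10 rose and 1 fell (11 and 1 adjusted over the list alone), with a median log2 fold change of 0.38 (camera adjusted p = 8.69e-05, and adjusted p = 0.319 with an estimated correlation). Egr3 rose 2.06-fold, from 1029 ± 20.1 to 2124 ± 39.5 normalised reads (SD, n = 2, limma adjusted p = 1.53e-04), and Egr1 rose 1.99-fold. Batf3, an AP-1 family member, fell to 0.501-fold. Junb was not called (21082 ± 1944 and 22290 ± 1193 normalised reads, limma adjusted p = 0.588). Among 30 cytokine and chemokine genes, 10 rose and 6 fell (11 and 6 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.181, but 0.0475 upward without TMP269 replicate 1). Beside Il2, the CD30 ligand gene Tnfsf8 rose 2.01-fold. Of 16 costimulatory and inhibitory receptor genes, 3 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.407, with 2 falling without TMP269 replicate 1). The activation marker Cd69 rose 1.98-fold and Cd274, which encodes PD-L1, rose 1.92-fold.

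Genes of the TGF-beta pathway and of naive and memory T cells also rose as groups. In the TGF-beta list 10 of 18 members rose and 1 fell (11 and 1 adjusted over the list alone), with a median log2 fold change of 0.40 (camera adjusted p = 0.00105, and adjusted p = 0.271 with an estimated correlation). Tgfbr2, a receptor subunit, rose 1.63-fold, from 2179 ± 144 to 3547 ± 44.2 normalised reads (SD, n = 2, limma adjusted p = 8.21e-04), while the ligand gene Tgfb3 fell to 0.376-fold. Of 14 naive and memory T cell genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone), with a median log2 fold change of 0.29 (camera adjusted p = 8.71e-04, adjusted p = 0.271 with an estimated correlation, fry adjusted p = 0.113). Foxp1, a factor of T cell quiescence, rose 1.63-fold and Ccr7, a lymph node homing receptor gene, 1.54-fold from 10170 ± 624 normalised reads. Without TMP269 replicate 2, 1 member of this list fell.

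Genes of glucose metabolism fell together. All 23 members of the glycolysis and hypoxia list were called lower, the same adjusted over the list alone, with a median log2 fold change of -0.72 (camera adjusted p = 3.90e-14, and adjusted p = 0.271 with an estimated correlation). Slc2a3, a glucose transporter gene, fell to 0.340-fold, from 5317 ± 324 to 1817 ± 311 normalised reads (SD, n = 2, limma adjusted p = 1.47e-04), and Ero1l, a hypoxia-induced oxidase of the endoplasmic reticulum, fell to 0.588-fold. Several members, Gapdh among them, have processed pseudogenes with which the counting could have split reads. The number called lower was 18 without TMP269 replicate 1 and 21 or 22 without any other library. In the unfolded protein and amino acid response list, 13 of 20 members fell and 2 rose (14 and 2 adjusted over the list alone), with a median log2 fold change of -0.48 (camera adjusted p = 1.85e-04, and adjusted p = 0.271 with an estimated correlation). The amino acid transporter gene Slc7a5 and the serine synthesis gene Phgdh fell to 0.520-fold and 0.523-fold. The 2 members that rose were Sesn2, a stress gene that is also in the p53 list (2.00-fold), and Ddit3, which encodes the stress factor CHOP (1.78-fold).

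Cell cycle genes fell by a smaller amount. Of 28 tested members, 0 rose and 15 fell (18 adjusted over the list alone), with a median log2 fold change of -0.32 (camera adjusted p = 5.16e-07, and adjusted p = 0.422 with an estimated correlation). The median was -0.22 with equal totals, where 5 members had a positive change and 23 a negative one. The other 13 members were not called, among them Mki67 and Top2a (log2 fold change 0.05 and -0.08, limma adjusted p = 0.740 and 0.570). The mitotic kinase genes Cdk1 and Aurkb fell to 0.677-fold and 0.685-fold, with Aurkb going from 3702 ± 47.4 to 2536 ± 28.4 normalised reads (SD, n = 2, limma adjusted p = 0.00163). Of 23 cholesterol synthesis genes, 0 rose and 3 fell, the same adjusted over the list alone (median log2 fold change -0.07, camera adjusted p = 0.677), and the median was 0.04 with equal totals and -0.01 without DMSO replicate 2. Fdps, a synthase of the mevalonate pathway, fell to 0.769-fold and Stard4, a sterol carrier, to 0.817-fold. The Fdps call was lost without TMP269 replicate 2 (limma adjusted p = 0.0888), with total library size in edgeR (0.0660) and with equal totals (0.0648). Without TMP269 replicate 2 the list had 0 called members. The Stard4 call was lost without DMSO replicate 2 (limma adjusted p = 0.129), TMP269 replicate 1 (0.124) or TMP269 replicate 2 (0.0813). It was also lost with total library size in edgeR (0.0879), library sizes without the 20 most abundant genes (0.0562), equal totals (0.0786) and equal totals without Rn45s (0.0689).

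Targets of p53, the stress-activated tumour suppressor, rose as a group. Of 16 tested members, 14 rose and 0 fell, the same adjusted over the list alone, with a median log2 fold change of 0.89 (camera adjusted p = 1.92e-11, and adjusted p = 0.271 with an estimated correlation). Trp53inp1, a p53-induced nuclear protein gene, rose 3.35-fold, from 3073 ± 47.8 to 10321 ± 1028 normalised reads (SD, n = 2, limma adjusted p = 4.36e-05), and Zmat3 rose 2.33-fold. The count of 14 was the same without any 1 of the 4 libraries. Interferon-stimulated genes also rose, 11 of 23 with 1 lower (12 and 1 adjusted over the list alone), with a median log2 fold change of 0.76 (camera adjusted p = 1.50e-04, and adjusted p = 0.271 with an estimated correlation). Irf7, a transcription factor of the interferon response, rose 3.59-fold from 53.7 ± 9.37 normalised reads, and Ddx58, which encodes the RNA sensor RIG-I, rose 1.70-fold. Gbp3, a guanylate-binding protein gene, fell to 0.608-fold. The number of interferon-stimulated genes that rose was 6 without DMSO replicate 2 and 7 without either TMP269 library. Their median log2 fold change was 0.48 without TMP269 replicate 1 and 0.51 without DMSO replicate 2.

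Among the targets of the compound, Hdac7 was at 8420 ± 725 normalised reads in DMSO and 11021 ± 1311 with TMP269 (SD, n = 2, log2 fold change 0.39 ± 0.11, limma adjusted p = 0.0273). Hdac5 was at 1360 ± 55.5 and 1616 ± 14.7 (log2 fold change 0.25 ± 0.08, limma adjusted p = 0.0481). Hdac4 (1155 ± 26.9 and 1190 ± 65.5) and Hdac9 (26.8 ± 4.78 and 25.9 ± 4.35) were not called (limma adjusted p = 0.747 and 0.927). The Hdac7 call was lost without DMSO replicate 2 (0.115) or TMP269 replicate 1 (0.211). The Hdac5 call was lost without any 1 of the 4 libraries (0.0553, 0.197, 0.214 and 0.159 without DMSO replicates 1 and 2 and TMP269 replicates 1 and 2) and also with DESeq2 (0.109) and without the filter on low values (0.0640). Ikzf3, which encodes Aiolos, rose 1.20-fold (limma adjusted p = 0.0356), a call lost without DMSO replicate 2 (0.137), TMP269 replicate 1 (0.255) or TMP269 replicate 2 (0.0958), and without the filter on low values (0.0508). Adjusted over the list of histone deacetylase and corepressor genes alone, only the Helios gene Ikzf2 passed (limma adjusted p = 0.00797). Hdac7 (0.0585), Hdac5 (0.0682) and Ikzf3 (0.0585) did not pass there. Of the 21 genes in this list, 4 rose and 0 fell, with 1 and 0 adjusted over the list alone (camera adjusted p = 0.407). The number that rose was 1 without DMSO replicate 2 or TMP269 replicate 1 and 2 without TMP269 replicate 2, and 2 members fell without DMSO replicate 1. MEF2 proteins are transcription factors that class IIa deacetylases repress. Of 13 MEF2 factors and known targets, 5 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.181). The immediate early genes Nr4a1 and Jun rose 1.403-fold and 1.36-fold. Mef2c, which B cells also express, fell to 0.268-fold, from 431 ± 8.44 to 115 ± 2.94 normalised reads, as the B cell markers did (list median log2 fold change -0.91). Mef2b fell to 0.553-fold (limma adjusted p = 0.0397), a call lost without DMSO replicate 1 (0.168) or TMP269 replicate 1 (0.118), with DESeq2 (0.116) and without the filter on low values (0.0672). It was also lost with total library size in edgeR (0.0770), library sizes without the 20 most abundant genes (0.0691), equal totals (0.0837) and equal totals without Rn45s (0.0740). In this list 3 members rose without DMSO replicate 1 or TMP269 replicate 2, and 1 fell without DMSO replicate 1 or TMP269 replicate 1.

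Markers of other spleen cells were mostly not called, except those of B cells. Of 10 B cell markers, 0 rose and 8 fell (9 adjusted over the list alone), with a median log2 fold change of -0.91 (camera adjusted p = 4.34e-06, and adjusted p = 0.271 with an estimated correlation). Bank1 fell from 440 ± 22.7 to 110 ± 14.3 normalised reads (SD, n = 2, limma adjusted p = 1.53e-04). Of 8 CD8 T and NK cell markers, 1 fell and 0 rose, the same adjusted over the list alone (median log2 fold change -0.06, and 0.05 with equal totals, camera adjusted p = 0.447, with 2 fallen without TMP269 replicate 2). The median of this list was -0.17 without DMSO replicate 1, -0.03 without DMSO replicate 2, 0.15 without TMP269 replicate 1 and -0.19 without TMP269 replicate 2. The called member was Klrk1, the NKG2D receptor gene, at 92.7 ± 19.1 and 23.2 ± 2.11 normalised reads. Of 9 myeloid markers, 1 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.604, with 2 risen without DMSO replicate 2 or TMP269 replicate 1). Cd68, a lysosomal membrane protein gene, rose 3.09-fold, and Mpeg1, a perforin-like gene, fell to 0.568-fold. Of 12 erythroid and platelet markers, 2 were tested, and Epor, the erythropoietin receptor gene, was 2.22-fold lower (1 lower adjusted over the list alone, list camera adjusted p = 0.694). The Epor call was lost without DMSO replicate 1 (limma adjusted p = 0.0551), where the other member was called higher.

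**Figure D3:**
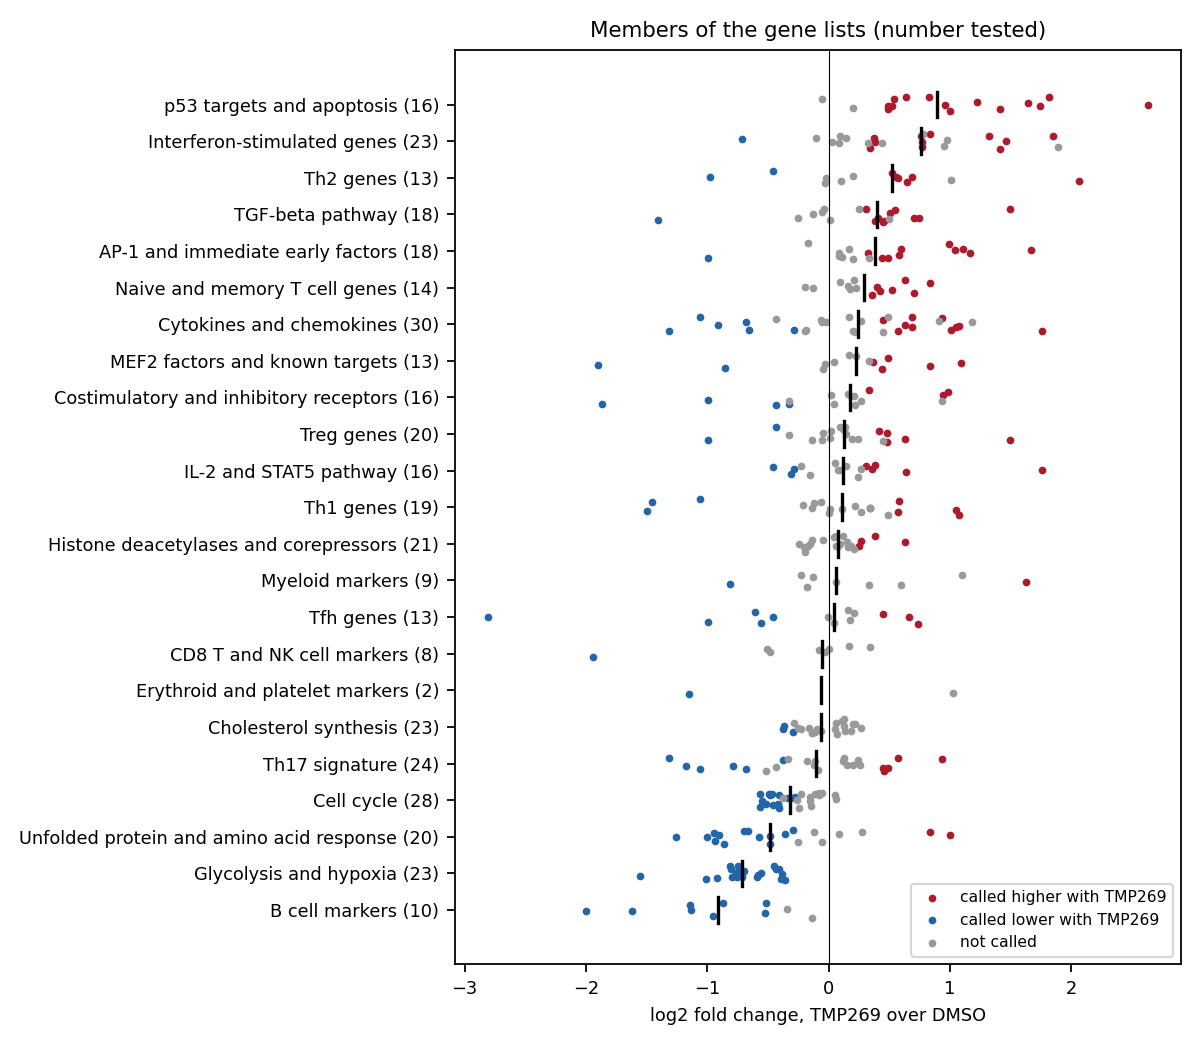
Each point is a tested member of 1 of the 23 gene lists, named on the y axis with the number tested, and the x axis gives its log2 fold change, TMP269 over DMSO. Black bars are list medians, which run from -0.91 for B cell markers to 0.89 for p53 targets, and colours mark members called higher, called lower or not called.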

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

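Other pseudocounts, TMM scaling in limma and equal totals were added after the data were seen. So was the edgeR test with TMM on recovered reads, which was the planned test apart from its filter. No called gene was called the other way in any alternative. Of 3448 calls, edgeR with TMM kept 3322, DESeq2 2782 and equal totals 2627. Genes called higher and lower numbered 3008 and 3352 with the replicate number as a block, which kept all 3448. The labels name no shared animal or day behind the replicate number. Yet differences between replicates 1 and 2 correlated across genes between groups at r = 0.371 (rho = 0.447). A condition shared by libraries of the same number would give such a correlation, but its source was not tested. The main test ignores such a pairing, and the block rests on 2 pairs. With the block, calls were gained for Il23r (limma adjusted p = 0.00503), Tbx21 (0.0122) and Rora (0.0330). Leaving out 1 library gave 1063 to 1802 higher and 1015 to 1873 lower, from fewer samples. Stricter thresholds gave 717 and 770 (adjusted p under 0.01) or 735 and 490 (at least 1.5-fold). Lower genes fell to 1053 with total library size in edgeR, 1042 with equal totals and 1151 with equal totals without Rn45s, which raise TMP269 values relative to DMSO. Of 23 lists, 9 passed with the preset correlation, 0 with an estimated one (lowest adjusted p = 0.271) and 10 with fry.

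Signs turned only for items that were not called. Left-out libraries gave log2 fold changes of -0.0144 to 0.0979 for Hdac4, -0.0118 to 0.177 for Junb and -0.223 to 0.130 for Hdac9. Hdac9 was at 0.0650 with total library size in edgeR, 0.0310 without the 20 most abundant genes, 0.0541 with equal totals and 0.0455 with equal totals without Rn45s. Fry gave the Th1 list an adjusted p of 0.483 downward. Left-out libraries gave camera adjusted p from 0.293 to 0.851 for Tfh and 0.424 to 0.832 for erythroid markers, each turning once, and no filter gave erythroid markers 0.968 upward. The cause was not tested. Of the values for named genes under alternatives, 1384 kept their side of the threshold and direction, 42 lost the threshold, 6 gained it and 8 turned. For lists these were 213, 10, 3 and 4. At these depths and with 2 libraries per group, 67.6% of simulated 1.5-fold and 83.3% of 2-fold changes were recovered. Only 200 genes had been changed, independently of each other and with the same dispersion for all genes, so the real data may differ. What depth alone limits was not tested.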

Other observations

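The lists and single genes in these observations, other than the lists of p53 targets, glycolysis genes and B cell markers, were chosen after the data had been seen. The tests of a shifted T cell share for p53 targets and of DMSO replicate 2 as the source were set only after the results they bear on were known. Cyp1b1, another xenobiotic-metabolising cytochrome P450, rose 4.96-fold beside Cyp1a1. Both are classical targets of the aryl hydrocarbon receptor, whose own gene Ahr fell to 0.771-fold (limma adjusted p = 0.0393). Of 6 further target genes, 3 were tested, and 3 of these 3 rose: Nqo1, a quinone reductase, 4.09-fold, Ahrr, the receptor's repressor, 2.01-fold and Tiparp 1.66-fold. These values are consistent with activation of the receptor in cells with TMP269, as a hypothesis. The data do not show whether the compound itself, or another change in the cells, would be the source.

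Genes of lysosomes rose, and genes of ribosome assembly fell. Flcn, a regulator of nutrient signalling at the lysosome, rose 2.21-fold and Tpp1, a lysosomal peptidase, 2.33-fold. A further list of 30 genes held mostly lysosomal genes, with some of autophagy (Sqstm1 and Uvrag) and nutrient signalling (Fnip1, Fnip2 and Rragd). Of these 30 genes, 20 rose, with Sqstm1, Fnip1 and Rragd among them, and 0 fell. The median log2 fold change of the list was 0.47 (camera p = 5.66e-11, but p = 0.0839 with an estimated correlation). Cln3 rose 1.90-fold and the protease gene Ctsd 1.74-fold. Beside falls of Myc and of the translation repressor gene Eif4ebp1 (to 0.423-fold), 17 of 21 tested ribosome biogenesis genes fell and 0 rose, with a median of -0.40 (camera p = 1.26e-08, but p = 0.166 with an estimated correlation). The rRNA methyltransferase gene Fbl fell to 0.670-fold and the nucleolar genes Ncl and Npm1 to 0.647-fold and 0.639-fold.

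The p53 targets rose by a list median of 0.89 on the log2 scale. Without DMSO replicate 2, the library with the most Rn45s reads, the median was 0.89, so the rise did not rest on that library. The called members already had both TMP269 libraries above both DMSO libraries, which left this check little room to come out otherwise. The pan-T cell genes, such as Cd3e and Cd4, had a median of 0.11 (SE of members 0.07), too little for a higher share of T cells to account for the rise. Of 12 further p53 targets, 9 rose and 0 fell, with a median of 0.75 (camera p = 3.59e-07, but p = 0.0964 with an estimated correlation), while Trp53 itself was not called (5103 and 4744 normalised reads). A p53 response is a candidate explanation, and it stays open whether stress from the compound, its dose or a shared culture condition would drive it.

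The fall of the glycolysis genes had a median of -0.68 without DMSO replicate 2, against -0.72 with all libraries, so it did not rest on that library. All members had been called, with both TMP269 libraries below both DMSO libraries, so this check too had little room to come out otherwise. The pan-T cell median of 0.11 argues against a lower share of T cells. A lower glycolytic activity of the treated cells was not measured, and a difference in culture density or growth between the groups stays open as untested.

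B cell markers, which naive CD4 T cells should lack, fell by a list median of -0.91, and a smaller number of B cells in the treated cultures is one candidate source. Among the abundant ones were Cd22, at 872 and 395 normalised reads, and Ms4a1, at 587 and 298, against 8281 and 9187 for Cd4, and purification of CD4 T cells would remove most B cells. The 14 further B lineage genes, some of which activated T cells also express, had a median of -0.20 (SE of members 0.15; 1 rose and 3 fell), so that fewer B cells cannot be told apart from no loss by this list, whose members went both ways. The values differed between markers, with Bank1 at 0.250-fold and Cd79b, which was not called, at 0.788-fold. A change of expression within B cells, or in T cells that express some of these genes, stays open beside a loss of B cells.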
